A study of Oncorhynchus tshawytscha with 56 samples.

How the data were processed

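The study profiled miRNAs by small RNA sequencing in hindgut, head kidney and spleen of full-sibling diploid and triploid Chinook salmon. Per the labels' protocols, fish were acclimated for 4 weeks in separate 200 L tanks at 8 degrees C for each ploidy, 10 fish of each ploidy were sampled before infection, and another 10 were sampled 3 days after a 100 µL intraperitoneal injection of bacteria at 400000 CFU per mL, given under sedation and followed by a recovery bath at 10 degrees C. RNA came from flash-frozen tissue, and libraries were made from 300 ng of RNA for hindgut and 100 ng for the other tissues. The submitters' processing notes name cutadapt 3.4, Bowtie 1.1.2 and featureCounts 1.5.0. Their settings, the genome build and the handling of reads that match several loci are not given in the sources used here.

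The deposited tables hold whole-number read counts per miRNA transcript ID, one table per tissue, which the authors had not normalized, judging by totals that differ between libraries. Each table has 298 IDs, of which 48 had no count in any hindgut library, 51 in head kidney and 51 in spleen. The head kidney and spleen tables hold the same fish and column names, so their tissue is taken from the initials in the table names alone. None of the IDs matched the reference gene table (0 of 298), which lists 0 genes of miRNA type. The files do not pair IDs with names, so no name is given, and the 21 miRNA family lists fixed before the data were examined could not be tested. The rule for named IDs, fixed at the same time, took up to 10 higher and 10 lower by p for comparisons over both ploidies and between tissues, 5 and 5 otherwise, and where fewer than 3 passed the 3 with the smallest p. It was narrowed to at most 2 in each direction because the IDs are unnamed.

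Groups and fish numbers come from the sample titles. All 56 libraries were used. Before averaging, 108 pairs of libraries of one group were compared, and the smallest chi-square per degree of freedom was 51.9, so none was a duplicate. Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM scaling, and the quasi-likelihood test with robust dispersion. Benjamini-Hochberg adjusted p under 0.05 passed. Within each tissue 1 fit held all 4 groups. Tissues were compared in 1 fit of the 48 libraries of the 16 fish with all 3 tissues. Standard errors are the log2 fold change divided by the square root of F. Alternatives fixed beforehand were RLE factors, library size only, no filter (1 count or more), DESeq2 1.42.0, only the groups compared, leaving out each fish, and, between tissues, the fish as a block, for which the filter was redone. Chosen after seeing the data were the summing of evenly split IDs, the exclusion of the diploid day 0 fish 4 and 8 in spleen and of fish 5, 8 and 9 in head kidney, and a blocked fit with the filter held as without the block, which was chosen after the blocked result was seen, so that only the block differed. Both versions are reported.

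The fish number marks the same animal across tissues in the titles, so it pairs libraries between tissues and not within a tissue. As a check, deviations from group means of the same fish correlated with a median r of 0.0496 between hindgut and head kidney, 0.108 between hindgut and spleen and 0.0627 between head kidney and spleen over 16 fish, against 0.012, -0.0288 and -0.029 for other fish of the group. With the replicate block the counts between tissues were 196, 184 and 156, and 16 IDs were called for a tissue-dependent day response. With the filter held these were 197, 183, 157 and 27.

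Some IDs share reads. In 33 groups holding 76 IDs and 19.8% of counts, members were linked by pairs whose counts were equal within binomial error. Each pair was judged by a chi-square summed over the libraries where it held at least 10 counts (p of at least 0.001). This held for 60 pairs, so in larger groups some members are joined only through another member. An even split is the pattern of reads from identical mature sequences being divided among loci, so group members are not independent, and 255 IDs remain when they are summed.

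The procedure was tested on counts simulated from the real means, library sizes and dispersions, with 40 IDs changed in each of 10 simulations, since the tables are too small for 200. Changes of 2-fold were recovered in 96.2% of cases for hindgut day 3 over both ploidies (221 IDs), 90.8% for head kidney and 91.5% for spleen (207 IDs each). For the interaction they were recovered in 73.1%, 30.8% and 43.8%, and changes of 1.5-fold in 25.0%, 5.71% and 11.4%. For the joint fit (227 IDs), 2-fold changes were recovered in 93.1% for hindgut against spleen and 76.2% for the tissue-dependent day response. False calls were between 1.99 and 5.93% of calls. Each ID was drawn independently and changes were balanced in direction, so shared reads, shifts common to many IDs and unusual fish were not simulated. The recovery and false call rates therefore do not cover those features of the real libraries. Depth limits low IDs: a head kidney library of 678269 counts holds fewer than 1 count for an ID at 1 CPM. Sequencing reads carry no molecular identifiers here, so counts are not independent molecules.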

Results

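MicroRNA levels were measured by small RNA sequencing in 3 tissues of full-sibling diploid and triploid Chinook salmon, sampled before (day 0) and 3 days after intraperitoneal injection of the bacterium Vibrio anguillarum, the agent of vibriosis. Triploid fish carry an extra chromosome set and are sterile. The tissues were hindgut, the last part of the intestine, and head kidney and spleen, the main blood-forming and immune organs of teleost fish. There were 6 fish in each ploidy and day group for hindgut (24 libraries) and 4 in each for head kidney and spleen (16 libraries each). Total miRNA counts ranged from 1565281 to 3269948 in hindgut, from 678269 to 1714272 in head kidney and from 1831910 to 3624671 in spleen. In head kidney the totals of diploid fish averaged 1580885 ± 91479 (SD, n = 4) at day 0 and 913408 ± 180512 (SD, n = 4) at day 3, which an exact two-sided permutation test separated at p = 0.0286, the smallest that 4 against 4 can give, or 0.171 after Benjamini-Hochberg adjustment over 12 such tests. Triploid fish at day 0, at 1206290 ± 61689 (SD, n = 4), differed from those diploid day 0 fish at the same p and adjusted p. The 10 most abundant miRNA IDs took 58.8 to 70.1% of counts in a hindgut library, 49.0 to 61.7% in head kidney and 58.8 to 69.3% in spleen. The miRNAs carry transcript IDs, and the files do not pair these with miRNA names, so each comparison names at most 2 IDs in each direction. Levels are TMM-normalized CPM, read counts relative to the scaled library total, and calls come from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Fish of each ploidy were held in separate tanks and no mock-injected group is among these samples. Per the labels, day 3 fish were also sedated for the injection and passed through a recovery bath at 10 degrees C before returning to tanks acclimated at 8 degrees C. The day comparison therefore covers injection, sedation, the bath, handling and time as well as bacteria, and the ploidy comparison covers tank.

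The hindgut gave the most calls of any tissue between days, from more fish than the others. Over both ploidies, ENSOTST00005076583 rose 1.81-fold at day 3 (log2 fold change 0.85 ± 0.11 SE, adjusted p = 9.00e-06), from 1708 ± 302 to 2895 ± 697 CPM in diploids and from 1558 ± 356 to 3002 ± 446 in triploids (SD, n = 6 each). ENSOTST00005021343 rose 1.77-fold (adjusted p = 9.00e-06). ENSOTST00005016464, an abundant ID, fell from 62878 ± 6426 to 47292 ± 3720 CPM in diploids and from 64939 ± 5962 to 46414 ± 4014 in triploids (log2 fold change -0.45 ± 0.06 SE, adjusted p = 9.00e-06). ENSOTST00005063185 fell by 1.25 on the log2 scale (adjusted p = 1.92e-05), to 61.5 ± 21.1 CPM in diploids and 43.8 ± 14.02 in triploids (SD, n = 6 each). For each of these 4 IDs, 12 of 12 day 3 fish lay beyond the day 0 median of their own ploidy in the direction of change. Of 221 IDs tested, 89 passed in edgeR's quasi-likelihood test, 49 higher and 40 lower at day 3. The median size of a passing change was 0.45 on the log2 scale. Dividing by library size alone moved the median of all IDs to -0.14 and gave 101 calls, 28 higher and 73 lower, so directions are relative to the TMM scale.

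**Figure D1:**
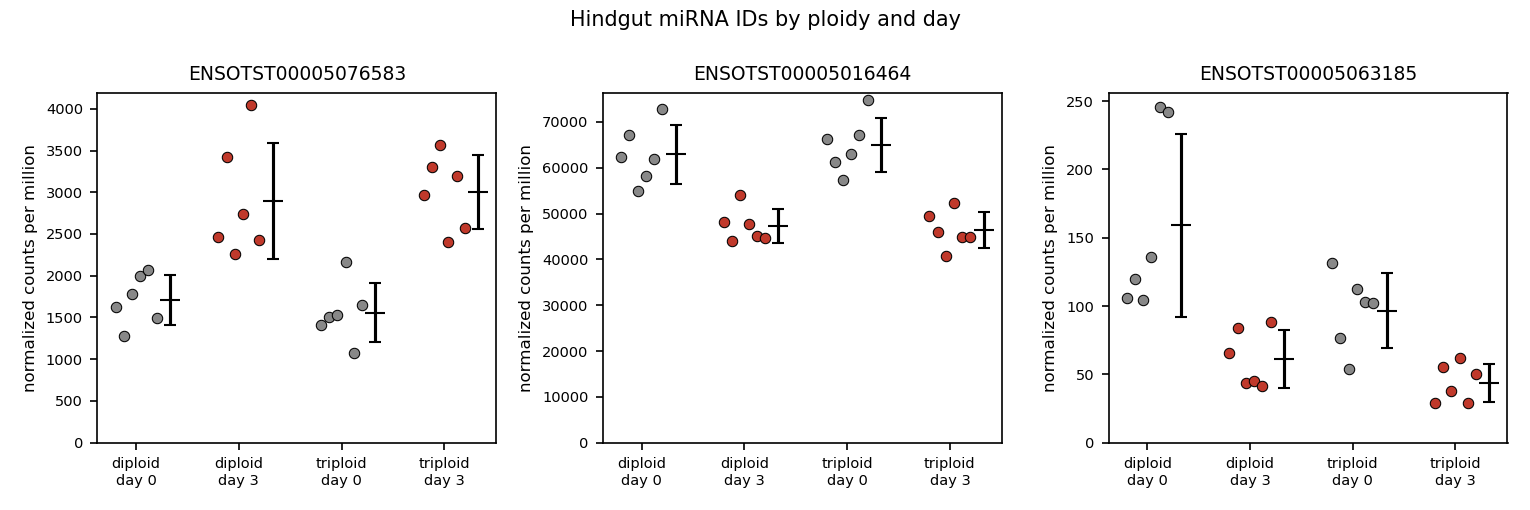
Normalized CPM of 3 miRNA IDs in hindgut, with a point for each fish (grey day 0, red day 3; n = 6 per group) and a bar at the group mean with its SD. ENSOTST00005076583 is higher at day 3 in both ploidies, while ENSOTST00005016464 and ENSOTST00005063185 are lower.

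Each ploidy taken alone gave calls in both directions in hindgut. In diploids ENSOTST00005001808 rose from 20407 ± 1778 to 32144 ± 3612 CPM (SD, n = 6 each; log2 fold change 0.66 ± 0.12 SE, edgeR adjusted p = 0.00109), and ENSOTST00005025863 rose 1.59-fold (adjusted p = 0.00109). ENSOTST00005063185 fell from 159 ± 66.7 to 61.5 ± 21.1 CPM (adjusted p = 0.00109) and ENSOTST00005016464 fell by 0.41 on the log2 scale (adjusted p = 0.00309). In triploids ENSOTST00005076583 rose 1.93-fold and ENSOTST00005021343 1.87-fold (both adjusted p = 6.26e-04), while ENSOTST00005016464 fell by 0.48 (adjusted p = 6.26e-04) and ENSOTST00005053717 by 0.43 on the log2 scale (adjusted p = 0.00392). Every one of the 6 day 3 fish lay beyond the day 0 median for each ID in its ploidy. In diploids 35 IDs passed, 18 higher and 17 lower, and in triploids 51 passed, 29 higher and 22 lower. With library size only, the medians moved to -0.18 and -0.16 and the splits were 12 higher and 50 lower in diploids and 13 higher and 37 lower in triploids. Fitting only the 2 groups compared gave 56 calls in diploids and 24 in triploids, and leaving out single fish gave 21 (without day 3 fish 21) to 57 (without day 3 fish 24) in diploids and 32 (without day 0 fish 11) to 59 (without day 0 fish 13) in triploids.

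Triploid and diploid hindgut differed in few IDs. At day 0, 3 IDs of 221 passed, all higher in triploids. ENSOTST00005055193 was at 709 ± 159 CPM in triploids and 453 ± 54.3 in diploids (SD, n = 6 each; log2 fold change 0.65 ± 0.15 SE, edgeR adjusted p = 0.0172), and ENSOTST00005082548 was at 221 ± 37.8 against 155 ± 15.4 CPM (log2 fold change 0.51 ± 0.12 SE, adjusted p = 0.0172). Both were above the diploid median in 6 of 6 triploid fish. Neither call held when only those groups were fitted (adjusted p = 0.0754 and 0.0780, 0 calls), although the log2 fold changes were nearly unchanged at 0.65 and 0.51, and the count was 0 without any 1 of diploid fish 1 and 10 and triploid fish 12, 16 and 19, and 5 without triploid fish 11 or 13. At day 3, edgeR called 0 IDs, with 20 at an unadjusted p under 0.05 and 0 by DESeq2. The smallest p belonged to ENSOTST00005076581, at 62.7 ± 11.4 CPM in triploids and 41.8 ± 6.63 in diploids (adjusted p = 0.122, or 0.0344 without diploid fish 30 and 0.0492 without triploid fish 38, and up to 0.741 with only these groups fitted). The day response did not differ between ploidies at the threshold for any ID: edgeR called 0, with 13 at an unadjusted p under 0.05 and 0 by DESeq2.

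In head kidney an abundant pair of IDs about doubled by day 3. Over both ploidies ENSOTST00005029342 rose 2.005-fold (log2 fold change 1.003 ± 0.16 SE, edgeR adjusted p = 0.00194), from 28789 ± 13836 to 53145 ± 6049 CPM in diploids and from 26980 ± 4527 to 58723 ± 4768 in triploids (SD, n = 4 each). ENSOTST00005066047 rose 1.76-fold (adjusted p = 0.00949). ENSOTST00005035111 fell by 2.73 (adjusted p = 0.00949) and ENSOTST00005013191 by 1.91 on the log2 scale (adjusted p = 0.0178). Each of the 4 moved the stated way against the day 0 median in 8 of 8 day 3 fish. The mean of ENSOTST00005013191 fell more in diploids, where day 0 fish were spread widely at 430 ± 304 CPM against 39.1 ± 2.98 at day 3, while triploids went from 79.9 ± 36.7 to 61.8 ± 20.9. The test of that difference between ploidies missed the threshold (edgeR interaction adjusted p = 0.179). Of 207 IDs tested, 9 passed, 3 higher and 6 lower, and library size alone gave 3 higher and 15 lower with the median of all IDs at -0.16. Single fish left out gave 4 (without diploid day 3 fish 21) to 16 (without diploid day 0 fish 4).

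**Figure D2:**
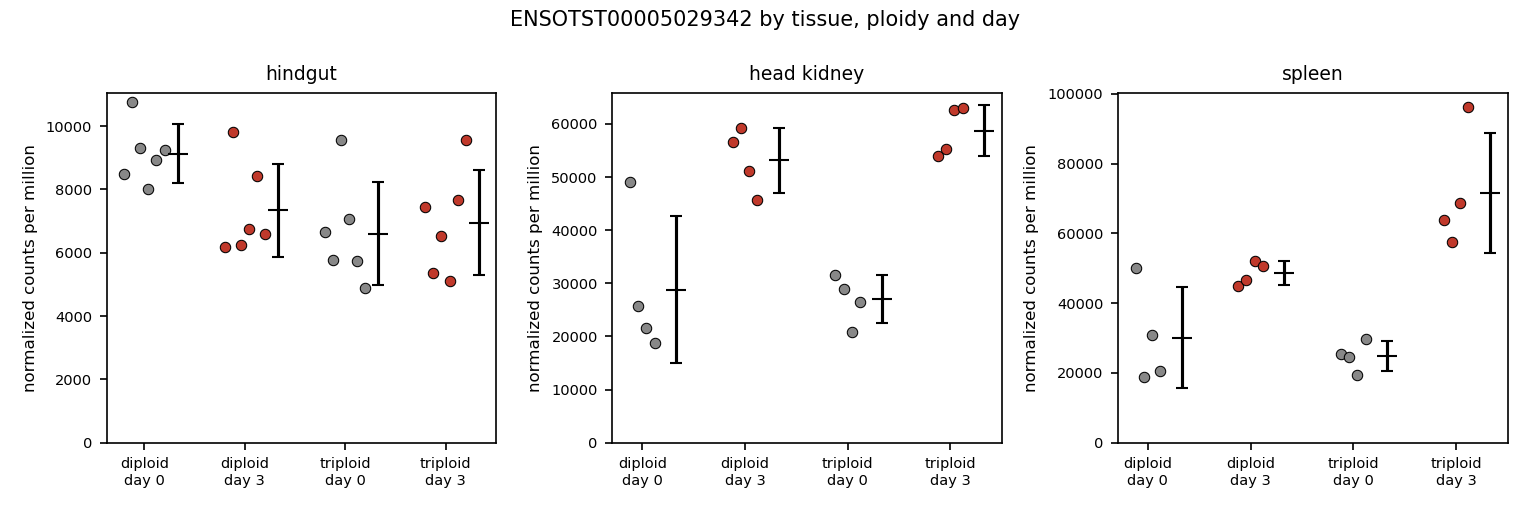
Normalized CPM of ENSOTST00005029342 in each tissue, with a point for each fish (grey day 0, red day 3; n = 6 per group in hindgut, 4 in head kidney and spleen) and a bar at the group mean with its SD. Means in head kidney and spleen are higher at day 3 in both ploidies, though the change in diploid spleen did not pass (log2 fold change 0.69, adjusted p = 0.0825), and a diploid day 0 fish lies near the day 3 level in each of these tissues.

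Within diploid head kidney, ENSOTST00005013191 fell by 3.46 ± 0.62 SE (edgeR adjusted p = 0.0112) and ENSOTST00005035111 by 4.09 ± 0.83 SE on the log2 scale (adjusted p = 0.0112), the latter from 25.5 ± 17.9 to 1.45 ± 0.69 CPM (SD, n = 4 each). ENSOTST00005005978 rose from 4425 ± 200 to 6065 ± 729 CPM and ENSOTST00005014927 from 3514 ± 306 to 4801 ± 482 (both adjusted p = 0.0381). All 4 held in 4 of 4 fish against the day 0 median. In all, 7 IDs passed, 3 higher and 4 lower, against 1 higher and 3 lower with library size only (median -0.11). No ID passed when only these groups were fitted or when day 3 fish 23 was left out (0 calls each), and 27 passed without day 0 fish 4. With only these groups the log2 fold changes of ENSOTST00005013191, ENSOTST00005005978 and ENSOTST00005014927 were -3.46, 0.45 and 0.45 (adjusted p = 0.230, 0.261 and 0.261), and the latter pair also missed with library size only (0.41 and 0.42, both adjusted p = 0.201). In triploids 1 ID passed, ENSOTST00005029342, which rose 2.18-fold (log2 fold change 1.12 ± 0.23 SE, adjusted p = 0.0292), and the next, ENSOTST00005066047, had a log2 fold change of 0.94 ± 0.24 SE and missed the threshold (adjusted p = 0.0904). That ID passed with library size only (adjusted p = 0.0438), no low-count filter (0.0393), DESeq2 (0.0135) and only these groups fitted (0.00118), and missed with RLE factors (0.0698) and in each fit without a fish (0.0654 to 0.184). DESeq2 called 14 in triploids and library size only called 8, of which 2 were higher and 6 lower (median -0.25). The call for ENSOTST00005029342 was lost in 5 of 8 fits that left out a fish, at log2 fold changes of 1.09 to 1.17.

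Head kidney gave no edgeR call between ploidies. At day 0 edgeR called 0 of 207 IDs, with 39 at an unadjusted p under 0.05 and 11 by DESeq2, and the count became 28 without diploid fish 4. ENSOTST00005013191 was at 79.9 ± 36.7 CPM in triploids and 430 ± 304 in diploids (SD, n = 4 each; adjusted p = 0.0699), and ENSOTST00005021344 at 7.10 ± 2.09 against 23.3 ± 7.23 (adjusted p = 0.0699). Over the alternatives fixed beforehand their adjusted p ran from 1.16e-04 to 0.180 and from 0.0152 to 0.180. The former passed by DESeq2 (3.33e-04) and without diploid fish 4, and the latter by DESeq2, with only these groups fitted (0.0311) and without diploid fish 4 (0.0360). Both passed with evenly split IDs summed (0.0460), an alternative chosen after seeing the data. At day 3 edgeR called 0, with 12 at an unadjusted p under 0.05 and 0 by DESeq2, and 2 without diploid fish 21. ENSOTST00005057858 was at 7540 ± 642 CPM in triploids and 10485 ± 1346 in diploids (adjusted p = 0.168, from 0.0465 without diploid fish 21 to 0.537 without triploid fish 31). The ploidy by day interaction gave 0 edgeR calls, 35 IDs at an unadjusted p under 0.05 and 8 by DESeq2, and 2 edgeR calls without diploid day 3 fish 21. Its smallest p belonged to ENSOTST00005013191 (log2 difference of day responses 3.09 ± 0.83 SE, adjusted p = 0.179), which passed by DESeq2 (0.00452) and without diploid day 0 fish 4 (6.57e-04) and reached 0.324 without triploid day 0 fish 11.

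Spleen shared the rise seen in head kidney for the same pair of abundant IDs. Over both ploidies ENSOTST00005029342 rose 2.16-fold (log2 fold change 1.11 ± 0.18 SE, edgeR adjusted p = 0.00221), from 30119 ± 14403 to 48628 ± 3413 CPM in diploids and from 24821 ± 4218 to 71593 ± 17147 in triploids (SD, n = 4 each), and ENSOTST00005066047 rose 2.01-fold (adjusted p = 0.00278). Both were above the day 0 median in 8 of 8 fish. ENSOTST00005080087 fell by 0.56 (adjusted p = 0.00853, 7 of 8 fish) and ENSOTST00005013807 by 0.55 on the log2 scale (adjusted p = 0.0333, 8 of 8 fish). Of 207 IDs, 16 passed, 11 higher and 5 lower, while library size alone gave 12 higher and 14 lower. The count ran from 9 without diploid day 3 fish 23 to 29 without diploid day 0 fish 9, and the call for ENSOTST00005013807 was lost in 8 of 16 such fits.

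In diploid spleen most passing IDs were lower at day 3. ENSOTST00005063185 fell from 8101 ± 2694 to 2418 ± 802 CPM (SD, n = 4 each; log2 fold change -1.74 ± 0.33 SE, edgeR adjusted p = 0.0123), and ENSOTST00005067202, one of the most abundant IDs, from 134930 ± 69020 to 54942 ± 6304 (adjusted p = 0.0424). ENSOTST00005055193 rose 1.67-fold (3 of 4 fish) and ENSOTST00005019188 1.76-fold (4 of 4 fish; both adjusted p = 0.0424). In all 30 IDs passed, 3 higher and 27 lower, against 6 higher and 15 lower with library size only (median 0.17). The count fell to 2, none shared with the 30, without the diploid day 0 fish 4 and 8 (an exclusion chosen after seeing the data), to 1 with no low-count filter or with only these groups fitted, and to 0 without day 3 fish 21 or 28 or day 0 fish 8, with 5 of 8 single exclusions moving it by over 1.5 times. Without fish 4 and 8 the log2 fold changes were -1.70 for ENSOTST00005063185 (adjusted p = 0.0628), 0.78 for ENSOTST00005055193 and 0.73 for ENSOTST00005019188, near those with all fish, while that of ENSOTST00005067202 shrank from -1.30 to -0.50. In triploid spleen ENSOTST00005006925 rose from 442 ± 56.3 to 1056 ± 145 CPM (log2 fold change 1.26 ± 0.21 SE, adjusted p = 0.00173) and ENSOTST00005029342 rose 2.88-fold (adjusted p = 0.00173). ENSOTST00005080087 fell from 584 ± 51.3 to 319 ± 72.6 CPM (adjusted p = 0.00500) and ENSOTST00005023867 from 494 ± 79.8 to 244 ± 98.7 (adjusted p = 0.0149). The last missed the threshold with only these groups fitted, at a log2 fold change of -0.96 (adjusted p = 0.0525) against -1.02 with all groups, and without day 0 fish 16 or day 3 fish 36. These 4 held in 4 of 4 fish, and 19 IDs passed, 10 higher and 9 lower. Library size alone gave 5 higher and 29 lower (median -0.14), DESeq2 called 40, and the count was 6 without day 0 fish 16 or day 3 fish 36.

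In spleen edgeR called IDs between ploidies at both days, but at day 0 chance could not be excluded, since 2 of 35 splits of the fish gave as many calls (highest other 20). At day 3 ENSOTST00005063185 was at 10563 ± 3724 CPM in triploids and 2418 ± 802 in diploids (SD, n = 4 each; 4.37-fold, log2 fold change 2.13 ± 0.33 SE, adjusted p = 0.00141), and ENSOTST00005054985 was at 1304 ± 734 against 309 ± 109 (adjusted p = 0.00399). ENSOTST00005080087 was lower in triploids, at 319 ± 72.6 against 537 ± 103 CPM (adjusted p = 0.0275), as was ENSOTST00005040763 at 1.90 ± 0.86 against 6.27 ± 2.53 (adjusted p = 0.0363). Each held in 4 of 4 triploid fish against the diploid median. The latter pair missed the threshold with library size only (log2 fold changes -0.75 and -1.71, both adjusted p = 0.0592), as did ENSOTST00005080087 with only these groups fitted (-0.73, adjusted p = 0.0771). At day 3, 9 of 207 IDs passed, 3 higher and 6 lower in triploids, against 10 higher and 7 lower with RLE factors and 3 higher and 0 lower with library size only. DESeq2 called 24 at day 3 and 24 at day 0. The count ran from 3 without triploid fish 31 to 17 without triploid fish 32. At day 0, 9 passed, 1 higher and 8 lower, against 2 higher and 7 lower with RLE factors and 2 higher and 5 lower with library size only (median 0.23). ENSOTST00005031993 was at 8.42 ± 3.04 CPM in triploids and 2.52 ± 1.56 in diploids (adjusted p = 0.0332), while ENSOTST00005021343 was at 247 ± 30.3 against 871 ± 515 and ENSOTST00005067202 at 52170 ± 7022 against 134930 ± 69020 (both adjusted p = 0.0280). Their log2 fold changes were 1.66, -1.82 and -1.37, nearly the same with only these groups fitted (1.68, -1.82 and -1.37), and 1.12, -0.87 and -0.57 without the diploid fish 4 and 8. No ID passed at day 0 without the diploid fish 4 and 8, with only these groups fitted, or without any 1 of triploid fish 11, 16 and 19 and diploid fish 4 and 8, and 22 passed without diploid fish 5, with 7 of 8 such exclusions moving the count by over 1.5 times.

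Between ploidies, edgeR called differences in the spleen day response, though splits of the fish left chance undecided. ENSOTST00005063185 fell in diploids and was at 6154 ± 2183 CPM at day 0 and 10563 ± 3724 at day 3 in triploids (SD, n = 4 each), a difference of day responses of 2.52 ± 0.46 SE on the log2 scale (edgeR adjusted p = 0.00823). ENSOTST00005054985 differed the same way, by 2.32 ± 0.52 SE (adjusted p = 0.0240). ENSOTST00005031993 and ENSOTST00005085660 differed the other way, by -2.54 ± 0.61 and -1.34 ± 0.33 SE (both adjusted p = 0.0240). Of 207 IDs, 32 passed, 24 with a more positive response in triploids and 8 with a more negative one, and 21 when evenly split IDs, which share reads, were summed (chosen after seeing the data). Library size alone gave 11 and 14 (median -0.27). The count fell to 0 without the diploid day 0 fish 4 and 8, where ENSOTST00005063185 had an unadjusted p of 7.20e-04 and an adjusted p of 0.131. The differences of the 4 IDs without those fish were 2.46, 2.49, -2.01 and -1.34 (adjusted p = 0.131 to 0.133), so the size of these 4 was largely kept. That need not hold for all 32. ENSOTST00005067202 and ENSOTST00005021343 also passed, and their day 0 ploidy differences shrank from -1.37 to -0.57 and from -1.82 to -0.87 without those fish. The count fell to 1 without any 1 of triploid day 0 fish 11 and 16, triploid day 3 fish 36 and diploid day 0 fish 8, to 9 without diploid day 3 fish 23 and to 11 without diploid day 0 fish 4.

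**Figure D3:**
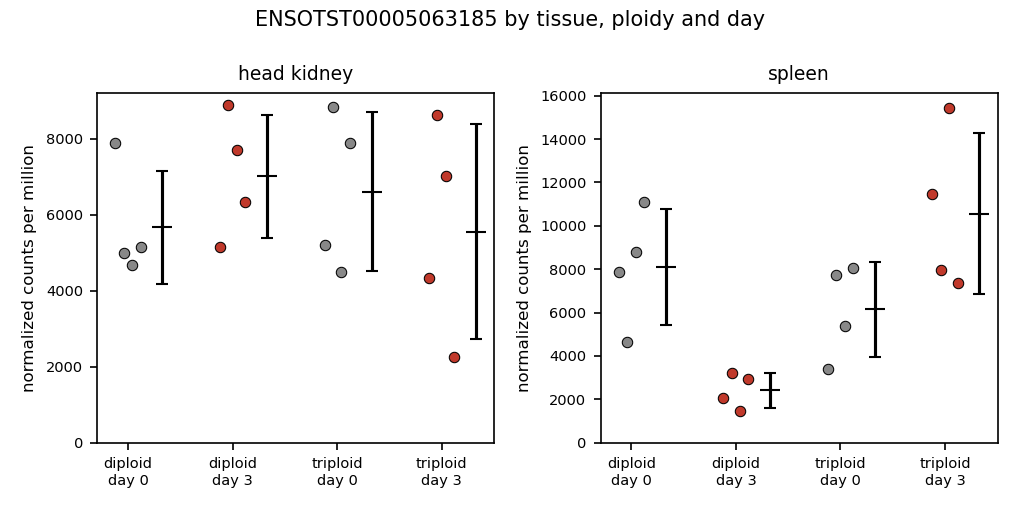
Normalized CPM of ENSOTST00005063185 in head kidney and spleen, with a point for each fish (grey day 0, red day 3; n = 4 per group) and a bar at the group mean with its SD. In spleen the diploid day 3 fish, at 2418 ± 802, are lower than the triploid day 3 fish, at 10563 ± 3724.

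The tissues had distinct miRNA profiles, compared in the 16 fish that gave all 3 tissues (48 libraries, 227 IDs tested). ENSOTST00005025863 and ENSOTST00005026255, an evenly split pair that cannot be told apart, marked hindgut. The former was at 25045 ± 5044 CPM in hindgut, 166 ± 48.01 in head kidney and 104 ± 41.4 in spleen (SD, n = 16 each), 246-fold above spleen (log2 fold change 7.94 ± 0.15 SE, edgeR adjusted p = 5.81e-38) and 150-fold above head kidney (adjusted p = 8.70e-37). ENSOTST00005030320 and ENSOTST00005016005, another evenly split pair, were lower in hindgut than in spleen by 3.67 and 3.66 on the log2 scale (adjusted p = 6.11e-33 and 1.85e-32). ENSOTST00005067811 was at 1.97 ± 0.89 CPM in hindgut and 137 ± 39.5 in head kidney, and ENSOTST00005087461 at 4.50 ± 1.58 against 339 ± 112 (adjusted p = 2.57e-30 and 1.09e-29). Between the blood-forming organs, ENSOTST00005058137 was at 77.8 ± 16.6 CPM in head kidney and 4.49 ± 2.45 in spleen, and ENSOTST00005020619 at 26.7 ± 6.17 against 0.65 ± 0.77 (adjusted p = 5.61e-24 and 3.44e-19). ENSOTST00005019996, the most abundant ID in spleen, was at 54363 ± 8225 CPM in head kidney and 246878 ± 45075 in spleen (adjusted p = 5.49e-25), and ENSOTST00005067057 at 592 ± 66.6 against 3108 ± 436 (adjusted p = 6.66e-28). Between hindgut and spleen 203 IDs passed (105 higher and 98 lower in hindgut), between hindgut and head kidney 183 (97 and 86) and between head kidney and spleen 159 (85 and 74). Library size alone moved the medians to 0.17, -0.34 and 0.63, and gave 82 higher and 112 lower for hindgut against head kidney and 147 higher and 37 lower for head kidney against spleen. Hindgut libraries were made from 300 ng of RNA and the rest from 100 ng, so input and tissue cannot be separated for hindgut.

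For 22 of 227 IDs edgeR called a day response that depended on tissue, though splits of the fish left chance undecided for this. ENSOTST00005065444 fell by 0.55 in hindgut and rose by 0.57 in spleen on the log2 scale (edgeR adjusted p = 1.22e-04 for the difference between tissues), with 0.37 ± 0.13 SE in head kidney (adjusted p = 0.163). ENSOTST00005058888 fell by 0.47 in hindgut and rose by 0.60 in spleen (adjusted p = 2.13e-04 for the difference). ENSOTST00005091455 rose by 0.59 in hindgut, with values of -0.29 ± 0.10 SE in head kidney and -0.02 ± 0.10 in spleen (adjusted p = 1.22e-04 for the difference). ENSOTST00005029342 rose by 1.04 in head kidney and 1.08 in spleen, with 0.01 ± 0.18 SE in hindgut (adjusted p = 0.00680 for the difference). Of the 22, 5 had a negative change in hindgut and positive ones in both other tissues, 5 had the opposite signs, 3 had the same sign in all and 9 another combination. These are signs alone, and in neither group of 5 did a head kidney change pass. Some values were near 0, such as -0.02 ± 0.12 SE in head kidney for ENSOTST00005067058. The 5 with opposite signs include ENSOTST00005043011 and ENSOTST00005094774, an evenly split pair. RLE factors gave 46 calls, library size only 47 and DESeq2 59. The fish as a block, which takes the pairing of tissues into account, gave 16. With the filter held as without the block, chosen after that result was seen, it gave 27.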

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

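All explanations weighed here, the exclusions of fish and the summing of evenly split IDs were tests chosen only after the result was seen.

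Of 164 groups of 4 or 6 fish checked for a library far from the rest (library totals and named IDs), 6 held one, and chance alone gives about 1 in 20. In hindgut triploid fish 12 at day 0 had the lowest total of its group, 2254831, and triploid fish 38 at day 3 had 229 CPM of ENSOTST00005082548 where the others had 183 to 198. In head kidney diploid fish 5 at day 0 had 4722 CPM of ENSOTST00005005978 against 4300 to 4369 in the others, and diploid fish 21 at day 3 had 2538 CPM of ENSOTST00005042844 against 3746 to 3766. In spleen triploid fish 14 at day 0 had the highest total of its group, 3097043, and triploid fish 36 at day 3 had 795 CPM of ENSOTST00005021343 against 217 to 299.

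A test of the difference itself called the day response different between tissues for ENSOTST00005065444 and ENSOTST00005091455 (both edgeR adjusted p = 1.22e-04), ENSOTST00005058888 (adjusted p = 2.13e-04) and ENSOTST00005029342 (adjusted p = 0.00680). For the last of these, the rise in head kidney and spleen, with that of ENSOTST00005066047, was weighed against technical explanations. A product of scaling is argued against: with library size only, or with the other abundant IDs left out, the smallest log2 fold change of both IDs in both tissues was 0.70. Whether the IDs share reads cannot be told apart from regulation in common, since the log2 ratio of the IDs varied by an SD of at most 0.11 within a tissue and both explanations allow that. Injection, sedation, the recovery bath at 10 degrees C, handling, tank time and infection all stay open as untested, as does a change in the cell makeup of these organs.

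The IDs that were lower at day 3 in diploid head kidney rest on high values in the day 0 fish 5, 8 and 9. Carry-over of hindgut RNA is argued against, because the IDs that mark hindgut allow at most 2.17% of hindgut RNA in a diploid day 0 library. At the highest hindgut level of each of the 4 IDs, that brings at most 8.83% of its lowest level in these 3 fish. Whether larger totals at day 0 matter was not decided. After thinning every library to the smallest total, the median log2 fold change of the IDs was -3.47, against -3.77 before. Of the 4 IDs, 1 to 4 still passed over 20 draws. Random thinning keeps relative levels, so the fold change was bound to stay near its first value. A difference between libraries that goes with their totals, RNA from another neighbouring tissue and real differences between fish stay open.

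The spleen day response was called different between ploidies for ENSOTST00005063185 (log2 difference 2.52), ENSOTST00005054985 (2.32), ENSOTST00005031993 (-2.54) and ENSOTST00005085660 (-1.34). The count did not rest on the 10 most abundant IDs, since 28 IDs passed after these were left out. That refit used TMM again, and library size alone changed the balance of directions, so a distorted scale stays open. The count of 32 depended on which of the 4 diploid day 0 fish were left out, and not only on how many. Without fish 4 and 8, 0 passed, and without fish 5 and 9, 54 passed. The other pairs gave 22 (fish 4 and 9), 8 (4 and 5), 4 (5 and 8) and 4 (8 and 9). That argues against the loss of 2 fish alone as the reason for the count of 0. The difference for ENSOTST00005063185 itself was 2.13 to 2.86 over these 6 exclusions. Ploidy and tank stay open as explanations that the design does not separate.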

How the results depend on the processing

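The summing of evenly split IDs, the exclusions of several fish at once and the blocked fit with the filter held as without the block were tests chosen only after the result was seen, and the other alternatives were fixed before the data were examined. Counts are IDs passing, and except where fewer IDs or fish enter a fit the cause was not tested. The counts of the hindgut day comparison over both ploidies and of each tissue pair stayed within 1.5 times of 89, 203, 183 and 159 under every alternative run, as did the hindgut interaction, at 0. The miRNA lists were not run, since no ID has a name.

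Library size only gave 62 for hindgut diploid day 3 against day 0 (35 with TMM), 18 for head kidney over both ploidies (9), 4 in head kidney diploids (7) and 8 in triploids (1), 26 for spleen over both ploidies (16), 34 in spleen triploids (19), 3 for spleen ploidy at day 3 (9) and 47 for the tissue-dependent day response (22). RLE factors gave 17 for spleen ploidy at day 3 and 46 for the tissue-dependent response. DESeq2 gave 14 for head kidney triploids, 11 for head kidney ploidy at day 0 (0 by edgeR), 8 for the head kidney interaction (0 by edgeR), 40 for spleen triploids, 24 for spleen ploidy at day 0 and 24 at day 3 (9 each by edgeR), and 59 for the tissue-dependent response. No low-count filter gave 11 for head kidney diploids, 3 for head kidney triploids and 1 for spleen diploids (30).

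Fitting only the 2 groups compared gave 56 for hindgut diploids, 24 for hindgut triploids (51), 0 for hindgut ploidy at day 0 (3), 0 for head kidney diploids, 3 for head kidney triploids, 6 for head kidney ploidy at day 0, 1 for spleen diploids, 0 for spleen ploidy at day 0 and 3 at day 3. Summing evenly split IDs gave 7 for head kidney ploidy at day 0 and 21 for the spleen interaction (32). Without the diploid day 0 fish 5, 8 and 9, head kidney gave 2 over both ploidies and 0 in diploids, and ENSOTST00005013191 changed sign, to 0.64 for ploidy at day 0 and -0.012 for the interaction, neither passing. Those fish were left out for their high values and a single diploid day 0 fish remains, assumed to vary like the other groups, so these losses say nothing about stability. Without the diploid day 0 fish 4 and 8, spleen gave 2 in diploids, 0 for ploidy at day 0 and 0 for the interaction.

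Leaving out single fish gave 21 to 57 for hindgut diploids, 32 to 59 for hindgut triploids, 0 to 5 for hindgut ploidy at day 0 and 0 to 1 at day 3. Head kidney gave 4 to 16 over both ploidies, 0 to 27 in diploids, 0 to 3 in triploids, 0 to 28 for ploidy at day 0, 0 to 2 at day 3 and 0 to 2 for the interaction. Spleen gave 9 to 29 over both ploidies, 0 to 30 in diploids, 6 to 22 in triploids, 0 to 22 for ploidy at day 0, 3 to 17 at day 3 and 1 to 37 for the interaction. Named IDs lost their call in 91 and gained one in 8 of these fits and kept their side in 641, with 39, 12 and 389 under the other alternatives. The replicate block changed no call of an ID named for a pair of tissues. Calls of the IDs named for the tissue-dependent day response were not followed under the block. The counts with the block, 196, 184, 156 and 16, were within 1.5 times of those without it, as were 197, 183, 157 and 27 with the filter held.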

Other observations

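All correlations, the splits of libraries and the position of fish 4 in this part were tests chosen only after the results they bear on were seen.

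Day responses of whole profiles were compared across 200 IDs tested in every tissue, with an exact two-sided permutation test over all 4900 relabellings of the 16 fish within ploidy. IDs are not independent replicates, which the relabelling allows for. Diploid and triploid hindgut had an r of 0.60 (exact p = 0.0106, 0.0637 after adjustment over 6 relations). The others were 0.045 for hindgut and head kidney (exact p = 0.739), 0.26 for hindgut and spleen (exact p = 0.155), 0.19 for head kidney and spleen (exact p = 0.505), -0.089 for the ploidies in head kidney (exact p = 0.732) and -0.16 for the ploidies in spleen (exact p = 0.632). None passed after adjustment, so a day response shared between tissues or ploidies was not shown by this measure, and relabelled fish gave an r as large as 0.82 in size.

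In spleen the ploidy by day difference of ENSOTST00005063185 was larger than in head kidney by 3.25 ± 0.72 SE on the log2 scale (edgeR adjusted p = 0.0137), and 10 of 227 IDs passed this test, which was run after the spleen result was seen.

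Diploid day 0 fish 4 had ENSOTST00005029342 near the day 3 level in head kidney and spleen. A candidate explanation is that the whole fish carries the wrong day label. Its hindgut library argues against that: placed on the triploid day response, with 0 the mean of the other diploid day 0 fish and 1 that of diploid day 3 fish, it lay at -0.089, among the other day 0 fish (-0.31 to 0.32) and below the lowest day 3 fish (0.53). For a wrong label on the head kidney and spleen libraries alone the same measure decides nothing, since days overlap there. Fish 4 lay at 1.09 in head kidney (other day 0 fish -4.65 to 4.79, day 3 fish -1.80 to 3.79) and at -1.20 in spleen (-1.98 to 1.36 and -0.83 to 1.97).

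Other splits of the libraries were counted for each result, up to 100 and drawn at random where more exist, with the real split included. Chance is called excluded where under 5% of splits gave as many calls, unless a limit is stated. There was no adjustment over the comparisons, and 1 of 35 is the smallest share that 35 splits can give. In hindgut the count of day 3 calls over both ploidies was 89, as many came from 1 of 100 splits and the highest other was 28, so chance can be excluded. The same holds for diploids (35, 1 of 100, highest other 4) and triploids (51, 2 of 100, with 1 other split above the real count at 62). For ploidy at day 0 the share is also under 5% (3, 2 of 100, highest other 3), but chance is not called excluded. There another split gave as many calls, 0 to 5 passed without a single fish and 0 with only those groups fitted. For ploidy at day 3 and the interaction the real count was 0, reached by 100 of 100 splits, with highest others of 17 and 9.

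In head kidney chance can be excluded for the calls over both ploidies (9, 1 of 100 splits, highest other 3, with 4 to 16 without a single fish) but not in diploids (7, 3 of 35, highest other 20). In triploids the share is also under 5% (1, 1 of 35, highest other 0), but it rests on a single call that was lost in 5 of 8 fits without a fish. Ploidy at day 0 and at day 3 gave 0, reached by 35 of 35 splits, with highest others of 7 and 1, and the interaction gave 0, reached by 100 of 100, with a highest other of 14. In spleen chance can be excluded over both ploidies (16, 2 of 100, with 1 other split above the real count at 18, and 9 to 29 without a single fish) and in triploids (19, 1 of 35, highest other 0, with 6 to 22). In diploids the share is also under 5% (30, 1 of 35, highest other 14), but chance is not called excluded. There 0 to 30 passed without a single fish, and 1 with only those groups fitted or with no low-count filter. Chance can also be excluded for ploidy at day 3 (9, 1 of 35, highest other 1, with 3 to 17 without a single fish), but not for ploidy at day 0 (9, 2 of 35, highest other 20). For the interaction 1 of 100 splits gave as many calls (32, highest other 14). Those splits exchanged ploidy labels within each day, so an equal ploidy difference at both days would also set the real split apart. They therefore leave chance undecided for the interaction, which gave 1 to 37 without a single fish. It gave 0 without the diploid day 0 fish 4 and 8 and 21 with evenly split IDs summed. Between tissues, with tissue labels exchanged within fish, 1 of 100 splits gave as many calls for hindgut and spleen (203, highest other 192), hindgut and head kidney (183, highest other 171) and head kidney and spleen (159, highest other 148). The tissue-dependent day response gave 22 with a highest other of 9 (1 of 100). Its splits exchanged day labels among fish of a ploidy, so a day response common to all tissues would also set the real split apart. Chance is therefore undecided for the difference between tissues.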
